A study of Mus musculus with 4 samples.

How the data were processed

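Aortic root and ascending aortic tissue of Tgfbr2 G357W/+ and wild-type littermate mice was digested and its cells sequenced with a 10x Genomics 3' assay, per the labels. Each of the 4 libraries pooled animals matched for age, genotype and sex, with 2 libraries per genotype. The submitters' processing notes name Cell Ranger 6.1.2, Seurat (no version) and the mouse build mm10, without saying what each did. One table of 19030 genes by 9373 cells was used.

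The deposited values are scores: whole numbers that the authors had brought to about 1 depth per cell, as the narrow band of cell totals shows. Which correction made them is not stated. The planned analysis had assumed raw counts, so its count models were not used. Genes were given by symbol, and 18781 of 19030 symbols (98.7%) were in GENCODE vM21, from which coordinates were taken (GRCm38). Ccn2, Ccn1 and Ecrg4 were found under the older symbols Ctgf, Cyr61 and 1500015O10Rik, through a RefSeq table of synonyms (GRCm38.p6). Every gene was seen in at least 3 cells. The cell and gene filters applied before deposit are not stated.

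Barcode suffixes gave 4 sets of cells, and the labels give no map from suffix to library. The analysis written for that case before the data were examined was used: all cells as 1 sample, classes, shares and gene levels, without a test between groups. The planned comparisons of genotypes and of sexes were not made. Cells are not replicates, so no p-value, SE or count of changed genes by genotype was computed.

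Values were scaled to 10,000 per cell and log-transformed (log(1 + x)). The 2000 most variable genes, without sex-linked genes, gave 30 principal components. A graph of 20 nearest neighbours, weighted by shared neighbours, was clustered with the Leiden method at resolution 0.5. That graph replaced an earlier one (fuzzy neighbour weights) after its clusters had been seen, because the new one could be repeated exactly. The earlier one was kept as an alternative. Macrophage-like cells were clustered again in the same way.

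Clusters were named from 22 marker lists fixed before the data were examined. The score of a list was the mean, over its genes, of a cluster's level divided by the highest cluster's level, and a name needed 3 markers detected in over 25% of cells. A cluster scoring under 0.5 with more leading genes from other lists than from its own stayed unnamed. This rule was set after the clusters were seen and kept 7.71% of cells (cluster 7) out of the named classes. The highest score of cluster 7 was 0.301, with 8 of 8 markers detected, against 0.233 for the fibroblast list. By its contractile transcripts that list was smooth muscle, so without the rule these cells would have joined the smooth muscle-like class. No alternative tested this rule. Names rest on transcripts, and a class named otherwise could differ.

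Doublets were left in. Scrublet, run per barcode set, called 51 cells (0.54%; 0.154, 0.266, 1.46 and 0.252% in sets 1 to 4). It expects raw counts, which these values are not, so it is treated as having barely worked. As a check, cells were counted whose transcripts of another lineage passed the 25th percentile of that lineage's own cells, and 6 cells (0.064%) did. A doublet carries only part of the transcripts of each lineage and can fall below that cut, so this count does not show that doublets were rare. Sub-cluster 6 of the macrophage-like cells carried fibroblast transcripts and was left out in an alternative.

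A gene's level is its summed depth-corrected counts per 10,000 of the class's sum. Log2 ratios are of level plus an offset of 0.1, which understates the change of low genes, and fibroblast-like clusters or macrophage sub-clusters that form 1 side of a ratio enter it as the mean of their levels. Endothelial-like cells, of 2 clusters, enter as 1 pooled class. The planned offset was 1, with 0.1 as its alternative, and 0.1 was taken after the data were seen. Lists, 34 in all, were fixed before the data were examined. They were compared over genes with a mean level of at least 0.2, in barcode sets with at least 20 cells of each cluster or pooled class compared, and a median was placed among 10,000 random lists of the same size matched on level. Directions shared by all sets describe these libraries and are not a test.

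Genes named were those of the rule fixed in advance, the 10 with the highest fold in each class among genes detected in at least 10% of its cells, and fixed genes of interest per class. Some genes that met this rule are not reported here. Members of the fixed lists were named beyond that rule after their values were seen. Leading genes were taken in the same way for fibroblast-like clusters and macrophage sub-clusters.

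Ratios and list medians were tested on simulated data, with 5082 genes drawn from fibroblast-like cluster 3 and 200 of them changed. All genes changed by a fold of 2 or 4 had the right direction in every set. The simulated sets were drawn from the same profile and differed by counting noise and total alone. Full recovery therefore checks the calculation and does not show how it performs on sets that differ as these do. Median recovered log2 values were 0.86 and −0.81 at a fold of 2, and 1.83 and −1.26 at a fold of 4. Of unchanged genes, 2.83% came out higher and 13.9% lower in every set, against 6.25% by chance. Levels per total shift when abundant genes change, so counts of genes moved in every set carry such a shift.

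Alternatives were a lower (0.3) and a higher (0.8) resolution, called doublets removed and no filter on low values, as planned. Added after the data were seen were the earlier graph, cells with at least 2000 genes, two-lineage cells removed, clustering without chemokine, cytokine and complement genes, an offset of 1, no sub-cluster 6, equal weight of the sets, and each set left out.

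Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.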

Results

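Single-cell RNA-seq profiles were collected from the aortic root and ascending aorta of mice aged 24 weeks. The mice carried the heterozygous Tgfbr2 G357W substitution, a model of Loeys-Dietz syndrome (an inherited aortic aneurysm disorder caused by altered TGF-beta signalling), or were wild-type littermates. The design held 4 pooled libraries, with 1 male and 1 female library of each genotype. The table analysed here held 19030 genes and 9373 cells, in 4 sets of cell barcodes of 1945, 2256, 2397 and 2775 cells. The labels did not map a barcode set to a library, and nothing in the table tied a set to a genotype. Sex-linked transcripts differed between the sets but do not give the genotype. The cells were therefore treated as 1 pooled sample, no comparison between Loeys-Dietz and wild-type mice was made, and no p-value was computed. Values are given over all cells, with the range over the barcode sets, which are not replicates of a group.

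The values of a cell summed to a median of 12800 depth-corrected counts, with a ratio of 1.21 between the 95th and the 5th percentile. The median per barcode set ran from 12340 to 13330. Cells had a median of 3136 detected genes, with 2025 and 4263 at the 5th and 95th percentiles, and no cell had more than 5.21% mitochondrial counts. The sequencing depth behind a cell was not recoverable from these values. Intervals on shares of cells are exact (Clopper-Pearson) 95% binomial intervals and cover the counting of cells alone. Gene levels are the depth-corrected counts of a gene per 10,000 of its cell class.

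The series asks, by its title, how fibroblasts that express the chemokine Ccl2 relate to macrophages in the aneurysmal root. The first part of that question, which cells were present, was addressed by clustering. The cells fell into 14 clusters, of which 13 were named from markers fixed before the data were examined. Fibroblast-like cells were the most abundant class, with 4246 cells or 45.3% (interval 44.3 to 46.3) and 43.5 to 46.4% over the barcode sets. Smooth muscle-like cells made up 16.2% (15.4 to 16.9), with 8.28, 12.1, 26.6 and 16% in sets 1 to 4. Valve interstitial and chondrocyte-like cells made up 15.9% (15.2 to 16.7), with 11.1, 14.9, 10.6 and 24.8%. That share was 27.8% at a lower and 6.32% at a higher clustering resolution, so its interval understates its uncertainty. Macrophage-like cells made up 8.92% (8.35 to 9.51), with 20.3, 13.3, 2.63 and 2.78%. At the higher resolution 521 cells had the macrophage name and a cluster of 315 cells the monocyte name, so this interval understates the uncertainty too. Endothelial-like cells made up 2.71% (2.39 to 3.06) and lymphatic endothelial-like cells 2.23% (1.94 to 2.55). The smallest named classes were 45 T cell-like, 34 mesothelial-like and 18 Schwann and glia-like cells. Cluster 7, with 723 cells or 7.71% (7.18 to 8.27), stayed unnamed by a rule set after the clusters were seen. Without that rule it would have counted as smooth muscle-like, so the interval on the smooth muscle-like share understates its uncertainty. At the lower resolution a cluster of 397 cells led by Igkc, Sfrp2 and Ankrd1, leading genes of cluster 7 too, took the fibroblast name instead. Its score was 0.31, against 0.10 for smooth muscle, so the name of such cells depends on the resolution. These shares describe the cells that survived enzymatic digestion, straining and a sort against debris, which can set them.

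**Figure D1:**
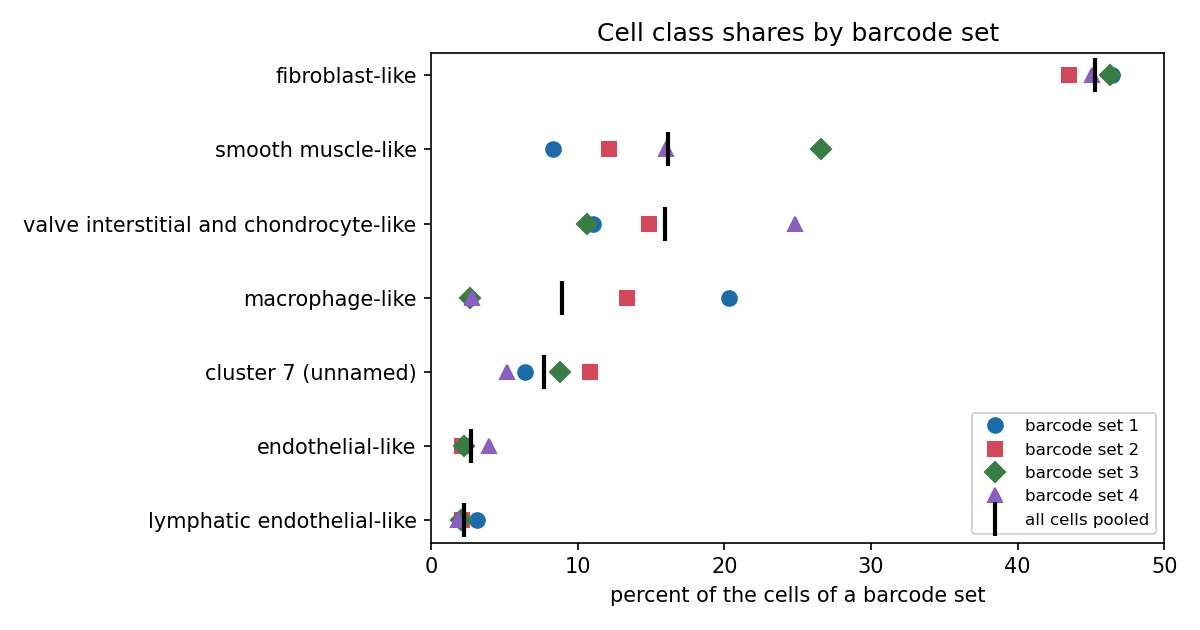
Share of cells (percent, horizontal axis) in each of 7 cell classes for barcode sets 1 to 4 (points) and for all cells pooled (black bar). Fibroblast-like cells lay between 43.5 and 46.4% in every set, and macrophage-like cells between 2.63 and 20.3%.

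Leading genes, those with the highest fold over the mean of the other classes, described the classes. Smooth muscle-like cells led with Myl9, Acta2, Cnn1, Myh11, Tagln, Tpm2, Sost, Lmod1, Itga8 and Ppp1r14a. Valve interstitial and chondrocyte-like cells led with Chad, Prg4, Ecrg4, Comp, Angptl7, Wif1, Epyc, Ucma, Npy and Thbs4. That name rested on 4 detected markers, with a marker score of 0.78 against 0.64 for the fibroblast list. Fibroblast-like cells led with Dpep1, Col6a5, Tnfaip6, Ptx3, Gpx3, Cygb, Hsd11b1, Cxcl5, Gfpt2 and Inmt. Macrophage-like cells led with Il1b, Ccl4, Lyz2, Chil3, C1qa, C1qb, Retnla, C1qc, H2-Aa and Cd74. Endothelial-like cells led with Flt1, Vwf, Ly6c1, Serpina1b, Pecam1, Fabp4, Selp, Ptprb, Gkn3 and Wnt9b, and lymphatic endothelial-like cells with Ccl21a, Mmrn1, Nts, Flt4, Gm21541, Lyve1, Cldn5, Lrg1, Prox1 and Klhl4.

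Tgfbr2, the gene that carries the substitution (chromosome 9, 116084293 to 116175360, GRCm38), was measured at 1.26 per 10,000 over all cells, with 1.03 to 1.45 over the sets. A 3' count does not read the substituted codon, so these levels check nothing about genotype. Lymphatic endothelial-like cells had the highest Tgfbr2 level, at 4.06 (3.79 to 4.38 over the sets). Fibroblast-like cells had 1.61 (1.28 to 1.82), endothelial-like cells 1.3 (0.943 to 1.57) and smooth muscle-like cells 0.429 (0.376 to 0.516). The Tgfbr2 log2 ratio of smooth muscle-like over fibroblast-like cells was −1.65 and lay between −1.73 and −1.40 in the 4 sets.

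Ccl2 (chromosome 11, 82035571 to 82037453, GRCm38) was highest in macrophage-like cells and next highest in a single fibroblast-like cluster. Macrophage-like cells had a Ccl2 level of 51.1 per 10,000, with 33.9, 45.5, 99.0 and 124 in sets 1 to 4. Fibroblast-like cluster 4, with 1175 cells, had 27.5, with 20.6, 41.7, 35.2 and 11.9. In each of the 4 sets the macrophage-like level was above that of cluster 4. The other fibroblast-like clusters had 5.93 (cluster 3, 4.10 to 9.56 over the sets), 8.16 (cluster 5, 4.08 to 17.1) and 8.64 (cluster 8, 5.34 to 12.8). In set 1 cluster 5, at 17.1, was close to cluster 4, at 20.6. Valve interstitial and chondrocyte-like cells had 1.86 and smooth muscle-like cells 0.146. The Ccl2 log2 ratio of cluster 4 over the mean of the other fibroblast-like clusters was 1.85, between 0.71 and 2.82 over the sets. It was also 1.85 when the cells were clustered without chemokine, cytokine and complement genes.

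Ccl2 was above 0 in 84.0% of macrophage-like cells and in 57.2% of the cells of cluster 4. After every cell had been thinned to 10,000 depth-corrected counts, the shares were 81.7% (interval 78.9 to 84.3) and 54.6% (51.7 to 57.5). Smooth muscle-like cells, taken for comparison, had 13.5% before and 11.4% (9.85 to 13.1) after thinning. Whether these values reflect expression or RNA of other cells was not tested, so they do not give a background. The median totals before thinning were 13680, 13190 and 12990 depth-corrected counts for these 3 groups. Those totals were already near even, so thinning could change the shares little. It does not even out the original sequencing depth, which is unknown. Ccl2 was not confined to these groups: after thinning the share was 41.0% in cluster 8, 38.8% in lymphatic endothelial-like cells, 37.6% in cluster 5 and 27.9% in cluster 3. Valve interstitial and chondrocyte-like cells had 22.3% and endothelial-like cells 19.3%.

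Because fibroblast-like cells were more numerous, they held more of the Ccl2 counts than macrophage-like cells did over all cells. Fibroblast-like cells held 52.0% of the Ccl2 counts (40.4 to 62.7% over the sets), with 30.9% in cluster 4 alone. Macrophage-like cells held 41.7% (33.0 to 51.9%). The order differed between sets. In set 4, macrophage-like cells held 51.9% and fibroblast-like cells 40.4%. In set 1 these classes were near even, at 47.7 and 48.1%, and in sets 2 and 3 fibroblast-like cells held more. The fibroblast-like counts include those of cluster 5, the most weakly named fibroblast-like cluster, with 8.6% over all cells and 11.5% in set 1. Without cluster 5, macrophage-like cells would hold more in set 1, and the classes would be near even over all cells. The Ccl7 counts were near even over all cells, with 48.9% in fibroblast-like cells (39.5 to 58.4% over the sets) and 48.1% in macrophage-like cells (38.1 to 58.2%). Macrophage-like cells held more of the Ccl7 counts in sets 1 and 4, and fibroblast-like cells in sets 2 and 3. The Ccl7 level was 7.27 in fibroblast-like cells and 34.9 in macrophage-like cells. Cxcl1 came mostly from fibroblast-like cells, with 69.4% of its counts (65.5 to 78.8%). Cxcl12 had 76.9% of its counts in fibroblast-like cells, at a level of 5 (3.61 to 7.67 over the sets). Macrophage-like cells held 98.9% of the Ccl4 counts and 91.3% of the Ccl8 counts, and lymphatic endothelial-like cells 99.5% of the Ccl21a counts. Ccr2, the receptor of Ccl2 (chromosome 9, 124101950 to 124113557), had 95% of its counts in macrophage-like and 3.77% in T cell-like cells. Cxcl1, Ccl4, Ccl8 and Ccl21a were chosen after their values were seen.

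**Figure D2:**
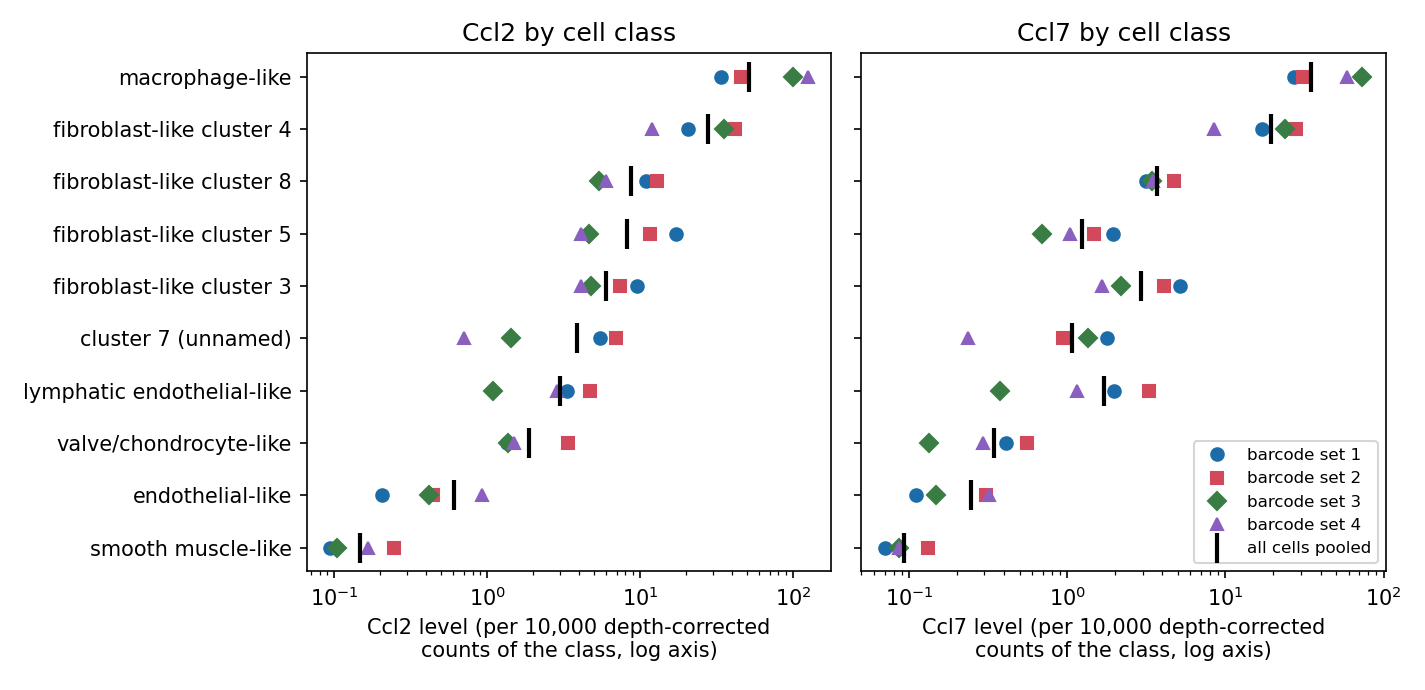
Levels of Ccl2 (left) and Ccl7 (right) per 10,000 depth-corrected counts, on log axes, in macrophage-like cells, 4 fibroblast-like clusters and 5 other classes, for barcode sets 1 to 4 (points) and all cells pooled (black bar). Ccl2 was 51.1 in macrophage-like cells, 27.5 in fibroblast-like cluster 4 and 0.146 in smooth muscle-like cells.

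The 4 fibroblast-like clusters were described by their leading genes. Cluster 3, with 1270 cells, had Hhip, Dio2, Cpxm2, Ntrk3, Fmod, Eln, F3, Hsd11b1 and Ntf3 among its leading genes. Cluster 4 led with Hp, Ccl11, Lcn2, Cxcl14, Ly6c1, Cxcl5, Col6a5, C3, Chl1 and Chil1. Cluster 5, with 1109 cells, led with Wif1, Cd74, H2-Ab1, H2-Eb1, H2-Aa, Nrgn, Coch, Cyp2e1, Prss35 and Npy. Cluster 8, with 692 cells, led with Gucy1a1, Ppp1r14c, Fhl2, Ptn, Igfbp3, Wisp2, Adamtsl2, Ccdc3, Angpt4 and Fgl2. Over the sets, cluster 4 held 15.9, 15.3, 9.14 and 10.9% of cells and cluster 5 held 9.77, 11.3, 7.43 and 17.5%.

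Gene lists fixed before the data were examined were then compared between cluster 4 and the other fibroblast-like clusters. A gene that moved at random would be higher in all 4 sets with a chance of 6.25%. Of 5345 genes tested, 938 were higher and 1702 lower in every set. Clusters differ in many genes, so the share of all genes, and not that chance, is the yardstick for a list. Where a comparison below is given without the share of all genes, its counts in every set describe the list. They do not show that the list stands out from all genes. Chemokine ligands had a median log2 ratio of 1.54, above all 10,000 random lists matched on level, and 8 of 13 genes were higher in every set. That median rested on the genes above the level minimum and was 0.29 when the low genes were kept. Cluster 4 was formed from these same values. Ccl11, Cxcl14 and Cxcl5 of this list, and Hp, Lcn2 and C3 of the complement and acute phase list, are among its leading genes. The medians and ranks of these lists therefore describe the cluster and are not tests. Ccl7 had a log2 ratio of 2.84 (2.00 to 3.44 over the sets), Cxcl1 1.54 (0.61 to 2.33) and Cxcl12 0.42 (−0.59 to 0.95). Cx3cl1 went the other way, at −1.09 (−1.34 to −0.93). Cytokines and NF-kB targets had a median of 0.89, with 9 of 14 higher and 1 lower in every set. Complement and acute phase genes had a median of 1.5, with 7 of 12 higher in every set. Adventitial progenitor-like genes, among them Pi16, Ly6a and Cd34, had a median of 1.80, with 8 of 9 higher in every set. The TGF-beta response list lay lower, with a median of −0.29 and 9 of 19 genes lower in every set, although Fn1, Ccn1 and Tgif1 of that list were higher. The immediate early and dissociation stress list had a median of −0.22, with 9 of 16 lower and 0 higher in every set. All 13 mitochondrially encoded genes were lower in every set, with a median of −0.30.

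The chemokine list median lay below 0 in each of the remaining fibroblast-like clusters when compared with the others, which include cluster 4. The list median was −1.32 in cluster 3, −0.77 in cluster 5 and −0.53 in cluster 8, with 12, 6 and 8 of 13 genes lower in every set. The list went both ways in cluster 5, where Ccl19, Cxcl10, Cxcl16 and Cx3cl1 were higher in every set. Cxcl12 was higher in cluster 3, at 0.44. Smooth muscle contractile genes were slightly higher in cluster 3, with a median of 0.70 and 10 of 11 genes higher in every set, and Acta2 at 6.09 against 2.44 per 10,000. The list of abundant smooth muscle transcripts, which overlaps it, moved alike (median 0.78, 6 of 6 higher), so smooth muscle RNA in these cells was not excluded. Elastin (Eln), a leading gene of cluster 3, was at 4.87 against 0.952. The stress list was higher in cluster 3 and in cluster 8, with a median of 0.21 in each, and 5 and 8 of 16 genes higher in every set. Over all genes 1117 of 5272 were higher in every set in cluster 3 and 952 of 5295 in cluster 8, so the count in cluster 3 was little above that of all genes.

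Cluster 5 combined transcripts of MHC class II presentation with low matrix transcripts. H2-Aa was at 4.91 per 10,000 in cluster 5 and at 0.107 in the mean of the other fibroblast-like clusters, a log2 ratio of 4.6 (3.67 to 5.23 over the sets). The ratio fell below that range at a lower clustering resolution. In cluster 5, 58.9% of cells had H2-Aa above 0. Fibrillar collagen and matrix genes had a median log2 ratio of −1.19, with 15 of 17 lower in every set, and elastic fibre genes −0.74, with 12 of 18 lower. Postn was the only matrix gene of that list higher in every set, at 13.3 against 1.93. Complement and acute phase genes had a median of −2.49, with 8 of 10 lower. Developmental patterning genes had a median of 1.24, with Tbx20, Gata4, Meox1 and Hand2 higher and Tcf21 and Enpep lower in every set. The class II genes helped to define cluster 5, so their difference is a description of it. The fibroblast name of cluster 5 was the weakest of the 4, with a marker score of 0.45 against 0.68 to 0.75. Its fibroblast transcripts were lower than in the other 3 clusters (median −1.16, 6 of 8 lower in every set), and at a lower clustering resolution its cells joined the valve interstitial and chondrocyte-like cluster. The fibroblast-like share of 45.3% includes its 11.8% of all cells.

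**Figure D3:**
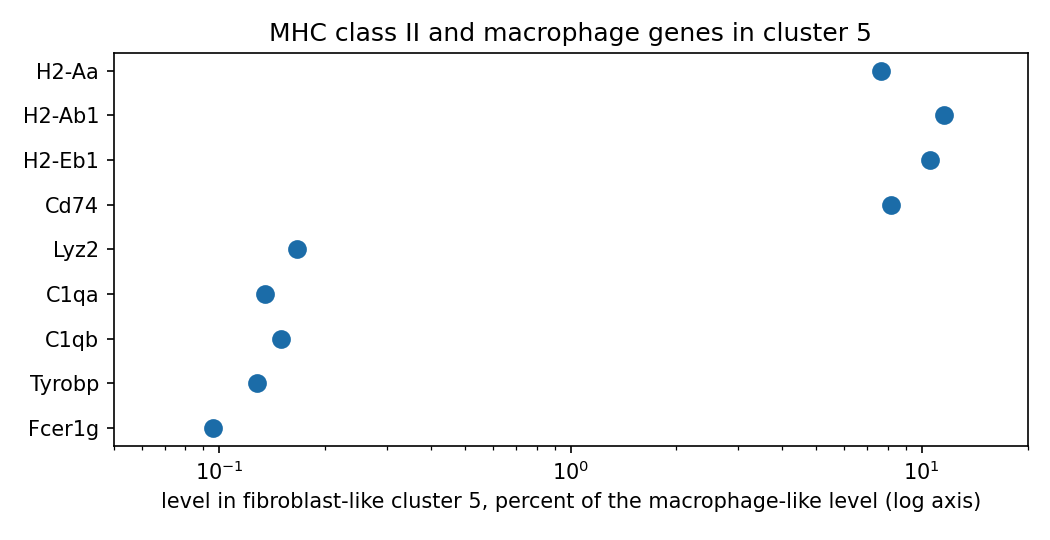
Level of 4 MHC class II genes and 5 macrophage genes in fibroblast-like cluster 5, as a percentage of their level in macrophage-like cells (horizontal log axis), over all cells pooled. The class II genes lay between 7.65 and 11.6% and the macrophage genes at or below 0.167%.

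Tgfb2 and Ccn2 were measured as TGF-beta readouts. In fibroblast-like cells Tgfb2 was at 1.16 per 10,000 (1.12 to 1.26 over the sets) and Ccn2 at 10.7 (8.02 to 14.3).

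Smooth muscle-like cells had Myh11 at 28.8 per 10,000 (26.0 to 33.9), Acta2 at 178 (167 to 187), Cnn1 at 13.2 (12.6 to 13.5) and Klf4 at 1.93 (1.27 to 2.33). Compared with fibroblast-like clusters, all 16 contractile genes were higher in every set, with a median log2 ratio of 4.43. The contractile genes are partly the markers that named the class. Chemokine ligands were lower in smooth muscle-like cells, with a median of −3.11 and 12 of 12 genes lower in every set. Oxidative phosphorylation genes, which named no class, were higher, with a median of 0.59 and 14 of 15 higher in every set. Mitochondrially encoded genes, which also vary with the quality of cells, moved with them (median 0.46, 12 of 13 higher).

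The unnamed cluster 7 carried contractile transcripts at an intermediate level. Its leading genes included Igkc, an immunoglobulin transcript, and Tnnt2, a marker on the cardiomyocyte list. Igkc does not describe cluster 7 in every set. Over all cells it was at 328 and 1980 CPM (from depth-corrected counts) in sets 1 and 2. In sets 3 and 4 it was at 0 and 0.285 CPM. Which cells of cluster 7 carried Igkc was not tested, so antibody-producing cells merged into this cluster in sets 1 and 2 were not excluded. Acta2 was at 48.1 and Myh11 at 6.36 there. Against smooth muscle-like cells, all 16 contractile genes were lower in every set (median −1.77) and 13 of 16 smooth muscle modulation genes were higher (median 2.30). Lists that can vary with the quality of cells moved too: 12 of 13 mitochondrially encoded genes (median −0.51) and all 15 oxidative phosphorylation genes (median −0.46) were lower, and 13 of 13 unfolded protein response genes were higher (median 0.76). Against fibroblast-like clusters, 15 of 15 tested contractile genes were higher (median 2.77) and all 8 fibroblast transcripts were lower (median −1.33). The TGF-beta response list was higher than in smooth muscle-like cells, with a median of 0.97 and 13 of 19 genes higher in every set. So were fibroblast transcripts (median 2.73, 7 of 8 higher) and the stress list (median 0.33, 11 of 16 higher). The stress list was also higher than in fibroblast-like clusters, with a median of 0.43 and 11 of 16 genes higher in every set. Valve interstitial and chondrocyte-like cells differed from fibroblast-like clusters by lower chemokine ligands (median −2.63, 12 of 12 lower in every set) and higher smooth muscle modulation genes (median 0.88, 11 of 16 higher). Spp1 was at 11.6 in that class.

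Macrophage-like cells had Il1b at 46.2 per 10,000, with 42.3, 58.8, 19.4 and 37.4 in sets 1 to 4. Ccr2 was at 1.39, with 1.45, 1.87, 0.111 and 0.190. Lyve1 was at 3.08, with 2.08, 2.44, 7.96 and 6.97. Spp1 was at 5.99, with 8.26, 5.63, 0.173 and 0.340. Trem2 was at 1.53 (1.28 to 2.04 over the sets) and Cx3cr1 at 0.585 (0.444 to 0.969). The class held 7 sub-clusters, and their mix differed between sets. Sub-cluster 1, led by Cd209f, Cd209g, Lyve1, Vsig4 and Fcna, held 245 cells, with 81, 63, 53 and 48 in sets 1 to 4. Sub-cluster 2, led by Arg1, Ccl24 and Chil3, held 147 cells, of which 143 were in set 1 and 4 in set 2. Sub-cluster 3, led by S100a8, Ccl17, Plac8 and Ly6c2, held 61, 75, 1 and 2 cells in sets 1 to 4. Sub-cluster 4, led by Lyz1, Serpinb2 and Retnla, held 39, 94, 1 and 4. Sub-cluster 5, led by Il12b, Cd207, Ifit2, Ifnb1 and Cxcl9, held 26, 38, 4 and 16. Sub-cluster 6, with 55 cells, led with fibroblast transcripts, Dcn and Mgp, and sub-cluster 7, with 28 cells, with proliferation genes, among them Top2a and Birc5.

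The same markers, applied to the sub-clusters, gave sub-clusters 1, 4 and 5 the macrophage name and sub-cluster 3 the monocyte name (score 0.67 against 0.31 for macrophage), and left sub-cluster 2 unnamed. The 10 leading genes of sub-clusters 1, 4 and 5 held no marker of the macrophage list, and those of 1 and 4 held a marker of another list (Lyve1 and Ifitm6), so these names rest on the score alone. In sub-cluster 3, 3 of 7 monocyte markers were detected. Its leading genes held 2 of them, beside S100a8 of the neutrophil list and Ccr7 of the dendritic list, so its name is uncertain. Ccl2 was highest in sub-cluster 1, at 106 per 10,000. It was at 37.9 and 54.9 in sub-clusters 4 and 5, at 17.3 in sub-cluster 2, and lowest in the monocyte-like sub-cluster 3, at 5.28. Within sub-cluster 1 the Ccl2 level was 83.7, 104, 112 and 139 in sets 1 to 4, a narrower range than that of the whole class. Against sub-clusters 3 to 5, which had at least 20 cells each in sets 1 and 2 alone, the Ccl2 log2 ratio of sub-cluster 1 was 1.69. All 14 resident macrophage genes were higher in both of these sets (median 3.11), of which several are leading genes of that sub-cluster. All 8 MHC class II genes were lower in both sets (median −1.99), and Ccr2 was at 0.248 against 1.77. All 16 immediate early and dissociation stress genes were also higher in sub-cluster 1, with a median of 1.47, so its Ccl2 level goes together with higher stress transcripts. These counts separate little, since of all 4801 genes tested 1891 were higher and 1709 lower in both sets, against a chance of 25% in each direction.

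Endothelial-like cells had Vcam1 at 10.4 per 10,000 (6.95 to 16 over the sets), Klf2 at 12.8 (10.5 to 14.7) and Edn1 at 2.46 (1.42 to 3.10). Compared with them, lymphatic endothelial-like cells had lower endothelial activation genes, with a median of −1.64 and 8 of 13 lower in every set. They had higher Ccl2, at 3.00 against 0.602 (log2 ratio 2.14, between 1.21 and 3.49 over the sets). The stress list was higher in lymphatic endothelial-like cells, with a median of 0.58 and 12 of 16 genes higher in every set.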

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

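All tests of explanations in this part were chosen after the result was seen. A barcode set was set apart where its gap to the nearest other set, divided by the range over the 4 sets, passed Dixon's 95% limit; 2 of 48 values did. Chance alone marks about 1 in 20.

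The endothelial-like share stood apart in set 4, with 3.93% of cells against 2.13 to 2.25% in the other sets (ratio 0.931). The share of macrophage sub-cluster 2, led by Arg1, Ccl24 and Chil3, stood apart in set 1, with 7.35% of cells against 0 to 0.177% in the other sets (ratio 0.976). A sub-cluster held almost wholly by a single set can be that library rather than a cell type. No technical explanation was tested for either value.

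The macrophage-like share, which passed no limit, differed 7.73-fold between the sets. Lower recovery of the main classes in some sets would raise macrophage-like and lymphatic endothelial-like cells alike. The ratio of macrophage-like to lymphatic endothelial-like cells was instead 6.48, 6.27, 1.29 and 1.51 in sets 1 to 4, a 5.04-fold range, which argues against that explanation. Without sub-cluster 6, which carried fibroblast transcripts, the share still differed 7.37-fold (18.8, 12.8, 2.55 and 2.67%). That sub-cluster held 55 of 836 macrophage-like cells, too few for its removal to level the shares. Its cells therefore do not account for the difference, but doublets with fibroblasts elsewhere in the class were not tested. The share also differed between sets alike in Xist: 20.3 and 2.63% in sets 1 and 3 (Xist at 5.03 and 4.72 CPM), and 13.3 and 2.78% in sets 2 and 4 (678 and 685 CPM). Sex alone would not give such differences. Genotype, sort or digestion, or sex together with any of these, may lie behind the share and stays open and untested.

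MHC class II transcripts in fibroblast-like cluster 5 could come from macrophage RNA, free or in doublets. The median class II gene in cluster 5 reached a fraction of its macrophage-like level 56.0 times the highest fraction of 5 macrophage genes (Lyz2, C1qa, C1qb, Tyrobp and Fcer1g), which argues against this source. Other leukocytes are argued against too: of 653 cells of cluster 5 with H2-Aa, 4.75% carried Ptprc, Laptm5, Coro1a, Cd52 or Cd79a, against 4.69% of cells of the other fibroblast-like clusters, a difference of 0.061 percentage points. Expression by the cells of cluster 5 themselves is the hypothesis left, found and tested on the same data. No biological explanation was tested.

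Ccl2 in fibroblast-like cluster 4 could come from the digestion or from macrophage RNA. In cluster 4 the immediate early and dissociation stress list had a median log2 ratio of −0.22 over the other fibroblast-like clusters. This argues against stronger general dissociation stress as the source of the Ccl2 excess of cluster 4 over them. More genes were lower than higher in every set in that comparison, so part of this median can be a shift of all genes. All clusters went through digestion, so the comparison cannot tell whether digestion raised Ccl2 in all of them. A digestion response of chemokines without immediate early genes stays open. Ccl2 reached 53.9% of its macrophage-like level in cluster 4, a fraction 342 times the highest of the 5 macrophage genes, which argues against macrophage RNA. A contribution of genotype was not tested.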

How the results depend on the processing

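Tests chosen after the data were seen were those with the earlier graph, the minimum of genes per cell, two-lineage cells, clustering without 3 gene lists, the offset of 1, sub-cluster 6, equal weight and sets left out. The lower and higher resolution, doublet removal and no filter on low values were planned.

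Of 343 values of 24 results under 15 settings, 314 stayed within the interval (shares) or the range of the 4 sets (other values), 29 moved beyond it and 0 reversed. A range over 4 differing sets is wide, so staying in it is a weak criterion.

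The smooth muscle-like share of 16.2% was 19.7% at lower resolution and 19.6% with the earlier graph, and 12.6 to 18.2% with a set left out. The fibroblast-like share of 45.3% was 37.6% at lower resolution, 54.9% at higher resolution and 44.1% in cells with at least 2000 genes; with a set left out it stayed within its interval. The macrophage-like share of 8.92% was 5.56% at higher resolution, where a monocyte-named cluster split off, 9.76% at equal weight of the sets, and 5.94 to 11.5% with a set left out (5.94% without set 1). At lower resolution the valve interstitial and chondrocyte-like cluster grew from 1492 to 2604 cells, as cluster 5 had merged into it. The smooth muscle-like cluster grew from 1516 to 1848 cells. At higher resolution a cluster of 902 cells led by Ucma, Prg4 and Npy took the fibroblast name (score 0.59 against 0.23 for the valve list). These moves thus went with how clusters were split and named. The cause of the remaining moves was not tested.

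The Ccl2 log2 ratio of cluster 4 (1.85) was 2.14 at higher resolution, 2.04 with the earlier graph, 1.73 with the offset of 1 and 1.58 to 2.21 with a set left out, all within the range of the sets. Values of other results that moved included the valve interstitial and chondrocyte-like share (27.8 and 6.32% at lower and higher resolution), the H2-Aa ratio (2.41 at lower resolution), the contractile list (3.77 at lower resolution) and the chemokine list of cluster 4, 0.29 instead of 1.54 with low genes kept. Ratios near the offset shrink with the offset of 1 by construction.

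Some definitions changed after output was seen. The H2-Aa ratio came out reversed at lower resolution while the cluster was picked among fibroblast-named clusters only, because its cells had merged into the valve interstitial and chondrocyte-like cluster; it is now picked among all clusters. The cluster followed when sets are left out is now fixed, after picking it anew by Col6a5 chose another cluster in a set. This changed the range over the sets and turned 3 Ccl2 ratios (2.14, 2.04 and 2.21) from moved to within range.

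No paired analysis was possible because cells are not mapped to samples and no result comes from a test. The planned models by genotype and their normalizations were not run for the same reason. Other denominators and removal of immediate early genes need no such map; they were planned for the genotype comparison and were not run on the pooled cells. A contrast by sex inferred from transcripts was not made, because the plan for unmapped cells held no test between groups. Barcode sets were left out in place of libraries. The planned minimum of 1000 UMIs could not be tested, because the original depth is unknown.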

Other observations

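No test in this part was planned; the values were looked at after the data were seen.

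Sex-linked transcripts were taken per barcode set. Xist was at 5.03, 678, 4.72 and 685 CPM (from depth-corrected counts) in sets 1 to 4, and Ddx3y at 120, 0, 99.6 and 0. Sets 1 and 3 carried Ddx3y with little Xist, the pattern of male cells. Sets 2 and 4 carried Xist without Ddx3y, the pattern of female cells. With 2 libraries of each sex in the design, these values do not single out a library or a genotype.

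Igkc, an immunoglobulin transcript, was at 328, 1980, 0 and 0.285 CPM in sets 1 to 4. Within the unnamed cluster 7 the Igkc level was 47.3 and 182 per 10,000 in sets 1 and 2 and 0 in sets 3 and 4. Hbb-bs, a hemoglobin, was at 66.3, 13.2, 271 and 247 CPM.

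The macrophage-like shares of 20.3, 13.3, 2.63 and 2.78% in sets 1 to 4 fell into separate clusters, as did the Ccr2 levels of these cells (1.45, 1.87, 0.111 and 0.190 per 10,000). T cell-like cells numbered 28, 15, 2 and 0.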
